A study of Mus musculus with 10 samples.

How the data were processed

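Hearts of 10 mice were profiled by RNA sequencing of poly(A) RNA. The labels give 5 libraries from mice with cardiac overexpression of SPOP, driven by Cre recombinase under the alpha-myosin heavy chain promoter (SPOP_CKI), and 5, titled wild type with the genotype of the Cre line, from control mice carrying the Cre transgene alone (Cre_control). All 10 animals are labelled male and the series describes them as 8 to 10 weeks old and under sham conditions. Per the labels' protocols, messenger RNA was captured on poly-T beads, fragmented and primed with random hexamers, and the strand setting is not given in the sources used here. Samples were grouped by the genotype and title in the labels. The titles number the hearts from 1 to 5 in each group.

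The deposited table holds 24888 genes. Per the submitters' processing notes, reads were counted per gene with featureCounts 1.5.0-p3 and compared with DESeq2 1.20.0 on mm10. The aligner and the annotation release are not given in the sources used here. The per-library columns deposited by the authors are a scaled read signal, that is, reads per gene divided by a size factor of the library. Dividing each column by the value of a single read gave whole reads for 100% of values at a tolerance of 0.001, and the value of a read times the median-of-ratios size factor of the recovered reads was 1.00 in each library. The authors also deposited the mean signal of each group, a log2 fold change, a p-value and an adjusted p-value per gene. In their adjusted p-value column, 7456 genes are listed at exactly 1 and 221 genes have no p-value. All per-sample columns of the table were used. Gene symbols, biotypes and coordinates are those of the deposited table. Of its gene identifiers, 99.9% were found in GENCODE M21 (GRCm38), with 100% of the matched genes overlapping the position given there, and transcript GC content was taken from that annotation for 99.9% of tested genes.

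Recovered depth was 15316293 to 17114869 reads per library. Within a group, no pair of libraries agreed within sampling noise (lowest chi-square per degree of freedom 13.8). Separate preparations of the same RNA could also differ by more than such noise, so this does not show that the libraries are separate animals. Each was counted as a replicate on the numbering in the labels. The labels number the hearts as repeats from mice and no more is stated on litters or batches, so p-values measure the spread between these libraries.

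Because the deposited values are scaled, the test was limma 3.58.1 (lmFit, then eBayes with an intensity trend and robust variances, in R 4.3.3) on log2(value + 1), with genotype as the sole term, over 14212 genes with a value of at least 10 in at least 5 libraries. Tests were two-sided with Benjamini-Hochberg adjustment at 0.05. Fold changes are on the log2(value + 1) scale, and a fold is that difference converted from log2. Such a fold differs from the ratio of the group means, and was larger than it for Scn4a, Adra1a and Ehhadh, which were at 0 in library SPOP_CKI 3. On data simulated from the means and depths of these libraries for the comparison of SPOP_CKI with Cre_control, over 13886 genes, the test recovered 20.4% of genes changed by 1 on the log2 scale and 77.9% of genes changed by 2, with 94 true and 5 false calls. Both groups were simulated with the same spread per gene, and no library was made an outlier. Far fewer genes were changed in the simulation than were called in the real data. The adjusted threshold was therefore stricter there, and these shares can understate recovery in the real data.

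Gene lists were written from textbook knowledge before the data were examined: 33 of pathways and 18 of cell type markers. They were tested with camera at a preset correlation of 0.01, with adjustment over the 46 lists that had at least 5 measured members. Camera with an estimated correlation and fry were run beside it. Each list is given as the number of members that passed the gene test, adjusted over all genes tested and adjusted over the list alone. The Spop level was also compared by an exact permutation test over all arrangements of the libraries.

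Genes named in the text follow a rule fixed before the data were examined. It takes Spop, Spopl and Cul3, 12 reference genes of cardiac hypertrophy and failure, and the 10 genes with the largest positive and the 10 with the largest negative fold change. The last were drawn from called protein-coding genes with an assigned symbol, a mean of at least 100 over the libraries and no overlap between groups. From each list described, up to 4 called members with the largest fold change were taken, or those with the smallest p where fewer than 2 passed. Other genes are said to have been chosen after their values were seen. Some genes that the rule takes are not reported here.

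Alternatives fixed before the data were examined were DESeq2 1.42.0 and edgeR 4.0.16 (quasi-likelihood) on recovered reads, TMM scaling, quantile normalization, no filter and a minimum of 50, pseudocounts of 0.5 and 5, the replicate number as a block, each library left out in turn, array weights, protein-coding genes alone, and an adjusted p under 0.01. Alternatives chosen after the data were seen were the exclusion of 3 libraries with Xist reads, the presence of Xist reads as a covariate, the centring of each library within 10 classes of transcript GC content, and edgeR and camera without library SPOP_CKI 3. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

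Several limits follow from gene-level values. Reads on Spop sum the endogenous gene and any transgene that keeps its sequence. Reads shared by near-identical copies (Acot1 with Acot2, Hba-a1 with Hba-a2, Hbb-bs with Hbb-bt, Hspa1a with Hspa1b) or by Myh6 and Myh7 can be split between them, and without a stated strand setting genes that overlap another tested gene (of those named, Nppa, Myh6, Myh7, Pln, B3galt2, Pfkfb1, Ucp3, Sbk2, Tnni3, Cacna1c, Bckdha, Timp4, Sod1, Klhl38, Fbxo32, Ccnd1, Ccnd2, Dbp, Pam, Plin4 and Tiparp) are uncertain to that extent.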

Results

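RNA sequencing was performed on the hearts of mice with cardiac overexpression of SPOP (SPOP_CKI, 5 libraries) and of control mice carrying Cre alone (Cre_control, 5 libraries). SPOP is the substrate-binding adaptor of a cullin-3 ubiquitin ligase. The study title places the comparison in the setting of pathological hypertrophy and heart failure, and the question addressed is how the cardiac transcriptome of SPOP_CKI hearts differs from that of controls. Depth was 15316293 to 17114869 reads per library, and values below are reads scaled by the authors' size factors, given as mean ± SD over 5 libraries per group unless stated.

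The overexpressed gene was examined first. Spop (ENSMUSG00000057522, mm10 chromosome 11, 95414080 to 95493406, plus strand) stood at 31897 ± 6254 scaled reads in SPOP_CKI and 3425 ± 317 in Cre_control (5 libraries each). Single libraries lay between 25308 and 40631 in SPOP_CKI and between 3078 and 3726 in controls, so that the lowest SPOP_CKI library was 6.79-fold above the highest control. The difference was 3.20 on the log2 scale (SE 0.17), or 9.20-fold (limma, adjusted p = 6.15e-06). An exact two-sided permutation test gave p = 0.0079, the smallest that 5 libraries per group allow. Its paralog Spopl, at 314 ± 51.4 against 285 ± 48.2, and the cullin scaffold Cul3, at 3046 ± 764 against 2737 ± 411, did not pass the test (limma, adjusted p = 0.591 and 0.627).

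Across the transcriptome, 3168 of 14212 genes changed (limma, adjusted p under 0.05), of which 1421 were higher and 1747 lower in SPOP_CKI. By over 1 on the log2 scale, 607 were higher and 1015 lower. The balance depended on the method. On recovered reads edgeR called 1685 higher and 1488 lower (803 and 811 by over 1), DESeq2 2115 and 2026 (934 and 1017), and the authors' deposited table lists 2038 and 1993 (1081 and 1165). The median fold change of all tested genes was −0.11 on the log2 scale and moved to 0.03 under quantile normalization. The count fell whichever control library was left out. It was 1935 without control library 1, 2109 without 2, 2289 without 3, 1947 without 4 and 2494 without 5. Leaving out an SPOP_CKI library gave 2358 to 4381. Without control library 4, 891 genes were higher and 1056 lower. Library SPOP_CKI 3 stood apart from the rest, as described below, and without it 1930 genes were higher and 2451 lower.

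**Figure D1:**
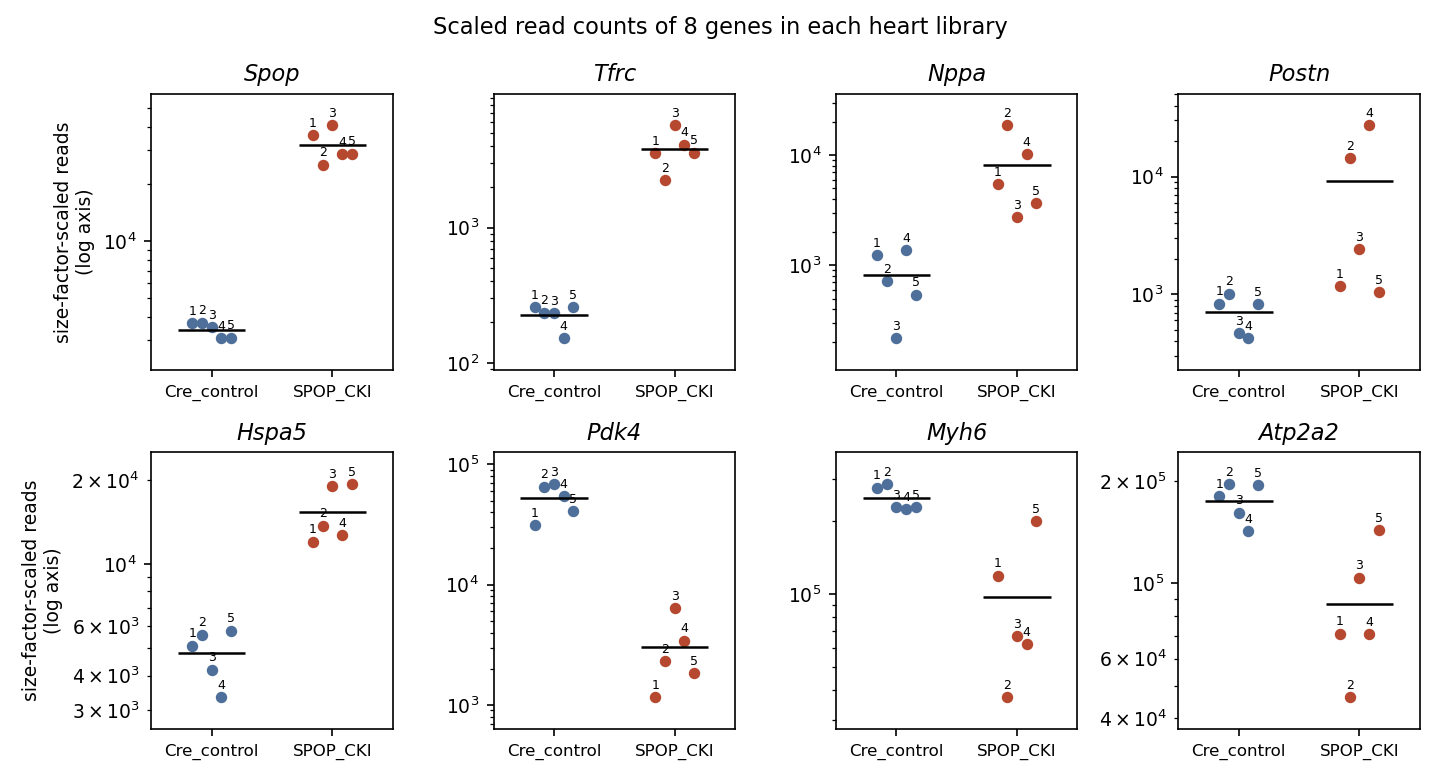
Size-factor-scaled reads (log axis) of 8 genes in each library, with the replicate number beside each point and the group mean as a bar. Spop, Tfrc, Nppa, Postn and Hspa5 lie higher and Pdk4, Myh6 and Atp2a2 lower in the 5 SPOP_CKI libraries on average.

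Among the genes with the largest increases and no overlap between groups, Tfrc (ENSMUSG00000022797, chromosome 16, 32608920 to 32632794), the transferrin receptor of cellular iron uptake, rose from 227 ± 43.8 to 3826 ± 1244 (log2 fold change 4.03, SE 0.24, adjusted p = 1.17e-05). The stress cytokine Gdf15 rose as well (log2 fold change 5.26, SE 1.04, adjusted p = 0.00601), from 15.1 ± 9.32 to 1318 ± 1573, with single SPOP_CKI libraries between 67.4 and 3746. Its log2 fold change was 4.54 without SPOP_CKI 2 and 5.99 without SPOP_CKI 3. Cyp1a1, a cytochrome P450 induced through the aryl hydrocarbon receptor, rose 34.7-fold from 5.57 ± 4.04 to 251.9 ± 182 (adjusted p = 0.00108). The chemokine genes Ccl7 and Ccl12 rose 24.3-fold and 13.8-fold, Ccl12 8.42-fold without SPOP_CKI 2. Scml4 (16.1-fold), Ndnf (14.2-fold), Nlrc3 (13.2-fold), Dio2, which encodes the deiodinase that activates thyroid hormone (12.6-fold), and B3galt2 (12.1-fold) completed the group (limma, adjusted p between 0.000229 and 0.0135 for these 7 genes besides Tfrc, Gdf15 and Cyp1a1).

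Among the genes with the largest decreases and no overlap between groups was Scn4a, which encodes a voltage-gated sodium channel (from 289 ± 84.7 to 14.7 ± 12.3, log2 fold change −4.95, SE 0.83, limma adjusted p = 0.00278). Acot1 (ENSMUSG00000072949, chromosome 12, 84009490 to 84018371), an acyl-CoA thioesterase gene, fell from 2792 ± 349 to 131 ± 75.4 (log2 fold change −4.61, SE 0.36, adjusted p = 8.68e-05). The mitochondrial uncoupling protein gene Ucp3 fell from 1705 ± 82.5 to 97.9 ± 72.7 (log2 fold change −4.36). Pdk4 (ENSMUSG00000019577, chromosome 6, 5483351 to 5496309), whose product restrains pyruvate dehydrogenase, fell from 52127 ± 16049 to 3031 ± 2060.5 (log2 fold change −4.29, SE 0.41, adjusted p = 0.000241). Ehhadh, a peroxisomal oxidation enzyme, fell by 4.48 on the log2 scale. The glycolytic regulator Pfkfb1 and the alpha-adrenergic receptor gene Adra1a had log2 fold changes of −4.64 and −4.08, and Tmem82, Smco1 and Sbk2 of −4.49, −4.41 and −4.05 (adjusted p between 0.00194 and 0.0125 for these 5 genes). Scn4a, Pfkfb1, Tmem82, Ehhadh, Adra1a and Sbk2 were at 0 in library SPOP_CKI 3, and without it they remained called with log2 fold changes of −4.15, −3.89, −3.54, −3.27, −3.05 and −3.19.

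Gene lists are described next. No list passed when the correlation within lists was estimated. In 40 of 100 splits of the 10 libraries at least as many lists passed as the 15 called here. Those splits all kept libraries SPOP_CKI 2 and SPOP_CKI 4 on the same side, so their number does not measure chance. Of 14 measured genes of the hypertrophic and fetal cardiac programme, 8 rose and 0 fell (1 fell without SPOP_CKI 1; 8 and 1 adjusted over the list alone), with a list median of 1.40 on the log2 scale (camera, adjusted p = 0.00223, and adjusted p = 0.527 with an estimated correlation). The natriuretic peptide genes Nppa and Nppb rose 9.34-fold and 4.25-fold, Nppa from 821 ± 485 to 8131 ± 6512 (log2 fold change 3.22, SE 0.59, limma adjusted p = 0.00446). The stretch-responsive genes Ankrd1, Fhl1 and Xirp2 rose 3.61-fold, 4.79-fold and 5.21-fold. The slow myosin gene Myh7 rose from 9225 ± 6984 to 45519 ± 26170 (log2 fold change 2.41, SE 0.64, adjusted p = 0.0207), a call lost with array weights and with no filter on low values. For Nppb, Myh7 and Xirp2 the groups overlapped. Nppb was at 4736 in SPOP_CKI 5, Myh7 at 10814 in SPOP_CKI 4 and Xirp2 at 5921 in SPOP_CKI 3, against 5123, 20635 and 5938 in control 5. Acta1 stood at 4732 ± 2406 against 3743 ± 1397 and did not pass (adjusted p = 0.708).

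Of 20 sarcomere genes, 6 fell and 0 rose (8 fell adjusted over the list alone, list median −0.54, camera adjusted p = 0.00343, and adjusted p = 0.616 with an estimated correlation), and quantile normalization ended that list call. Without SPOP_CKI 2 or 5, 1 rose. Tcap fell 7.11-fold, Lmod2 fell 2.22-fold, and the fast myosin gene Myh6 fell from 249198 ± 29585 to 97162 ± 64722 (log2 fold change −1.59, SE 0.39, limma adjusted p = 0.0145). Centring each library by transcript GC content, chosen after the data were seen, ended the calls of 30 of the 162 called genes the naming rule takes, Myh6 and Tnni3 among them (Tnni3 log2 fold change −1.24). Calcium-handling genes went both ways, with 5 of 19 higher and 5 lower (5 and 6 adjusted over the list alone, camera adjusted p = 0.799). Without control library 1, as without control library 2, 2 were higher and 2 lower. With control library 3 or 4 left out 3 were higher and 3 lower, 3 were higher without SPOP_CKI 1 and 3 lower without SPOP_CKI 4. Among them Atp2a2, the calcium pump of the sarcoplasmic reticulum, fell 2.15-fold (adjusted p = 0.0199), a call lost without control library 1 or control library 2, and Cacna1c fell 2.06-fold. Pln stood at 22031 ± 12796 against 24535 ± 5609 (adjusted p = 0.552). Of 21 ion channel and gap junction genes, 4 fell and 2 rose (5 and 2 adjusted over the list alone, camera adjusted p = 0.254). The number lower was 2 without control library 1 and 7 without SPOP_CKI 5, and 1 was higher without control library 1, 2, 3 or 5 or without SPOP_CKI 2 or 4. Scn4b fell 12.0-fold and Kcnip2 3.68-fold, while the connexin gene Gja1 rose 2.65-fold.

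Fatty acid oxidation genes fell together, 24 of 27 lower and 0 higher (25 lower adjusted over the list alone), with a median of −1.34 on the log2 scale (camera, adjusted p = 1.02e-11, and adjusted p = 0.519 with an estimated correlation). Without library SPOP_CKI 3, 25 were lower. Besides Pdk4 and Ucp3, Acot2 fell from 4179.7 ± 820.5 to 722 ± 353 (6.28-fold, adjusted p = 0.000525). Of 23 genes of the tricarboxylic acid cycle and branched-chain amino acid breakdown, 16 fell and 0 rose (18 fell adjusted over the list alone, median −0.92, camera adjusted p = 4.01e-08, and adjusted p = 0.519 with an estimated correlation). Bckdha and Bckdhb, which encode the branched-chain ketoacid dehydrogenase, fell 4.63-fold and 2.69-fold, and Ivd fell 3.10-fold. Nuclear genes of oxidative phosphorylation numbered 18 of 40 lower and 0 higher (24 lower adjusted over the list alone, median −0.71, camera adjusted p = 1.45e-07, and adjusted p = 0.616 with an estimated correlation). Without library SPOP_CKI 3, 31 were lower, and without control library 1, 11. The heart and muscle isoform genes Cox6a2 and Cox7a1 fell 4.04-fold and 3.56-fold. Of the ventricular cardiomyocyte markers, 6 of 12 were also lower.

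Of 13 mitochondrially encoded transcripts, only mt-Co2 passed, lower at 9319 ± 4525 against 29081 ± 12657 (adjusted p = 0.0191), and its call was lost without control library 1 or control library 2 (1 adjusted over the list alone, list camera adjusted p = 0.0502). The list passed without control library 4, where 2 transcripts were lower, and without SPOP_CKI 5, where 3 were. Regulators of mitochondrial biogenesis and dynamics had 1 of 15 higher and 3 lower (1 and 3 adjusted over the list alone, camera adjusted p = 0.825). The number lower was 1 without any of the 5 control libraries or without SPOP_CKI 2 or 4, and the number higher was 0 without control library 1 or 4 and 2 without SPOP_CKI 2. Tfb2m fell 1.48-fold, and Ppargc1a, at 2027 ± 1068 against 1567 ± 399, did not pass (adjusted p = 0.74). In glucose metabolism 10 of 27 genes fell and 3 rose (12 and 5 adjusted over the list alone, camera adjusted p = 0.223), with the insulin-responsive glucose transporter gene Slc2a4 3.16-fold and Pdk2 3.21-fold lower. Without control library 1, 2 or 4 or without SPOP_CKI 4, 6 were lower, and without SPOP_CKI 3, 6 were higher. Of 24 genes of lipid synthesis, storage and ketone metabolism, 12 fell and 6 rose (13 and 6 adjusted over the list alone, camera adjusted p = 0.177, fry adjusted p = 0.000684). Angptl4 fell 15.8-fold (24.0-fold without SPOP_CKI 2), the triglyceride lipase gene Pnpla2 4.92-fold and the lipid droplet gene Plin5 4.28-fold.

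**Figure D2:**
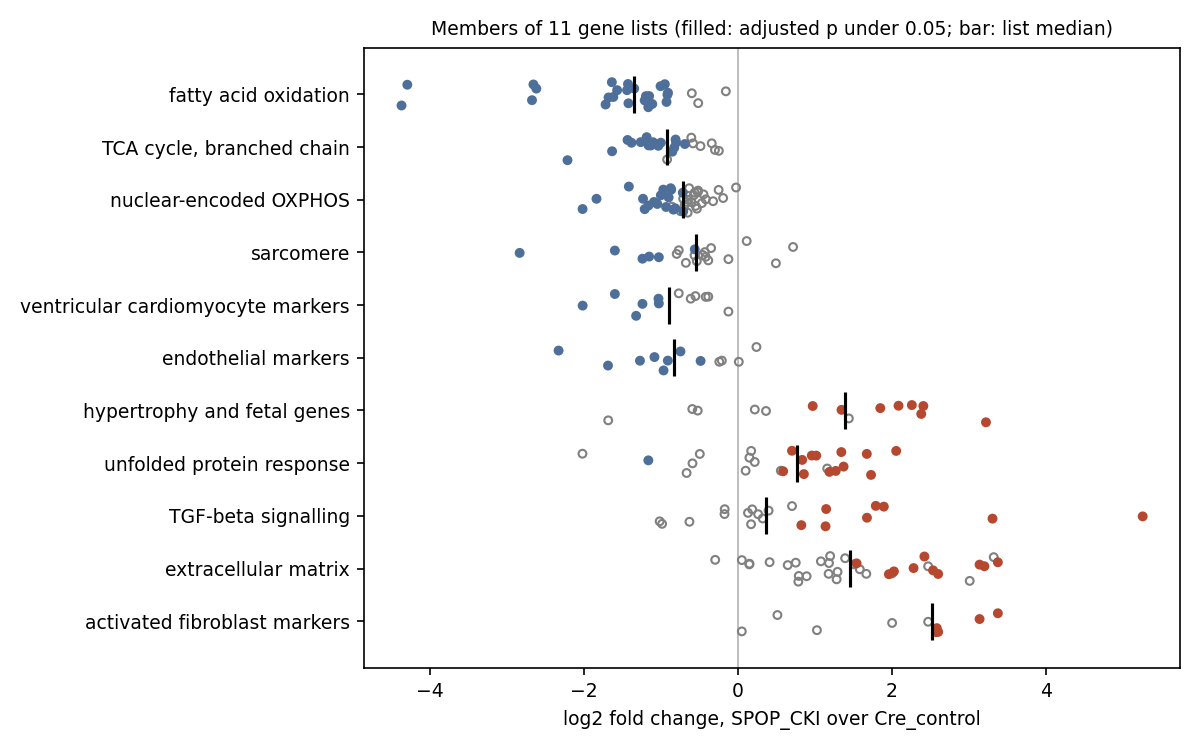
Log2 fold change (SPOP_CKI over Cre_control, horizontal axis) of each measured member of 11 gene lists. Filled points passed at an adjusted p under 0.05, open points did not, and the vertical bar is the list median, which is −1.34 for fatty acid oxidation and 2.52 for activated fibroblast markers.

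Of 34 extracellular matrix genes, 10 were higher, 0 were lower and 24 did not pass (17 higher adjusted over the list alone, median 1.45, camera adjusted p = 1.45e-07, and adjusted p = 0.616 with an estimated correlation). By fry the list did not pass (adjusted p = 0.0673). Without library SPOP_CKI 3, 21 were higher, and without control library 2, 3 or 4, 6 were. The spread among SPOP_CKI hearts was wide. Postn, a matricellular gene of activated fibroblasts, averaged 9204 ± 11451 against 712 ± 254 (log2 fold change 2.60, SE 0.84, adjusted p = 0.0474), with 14247 and 27145 in libraries SPOP_CKI 2 and SPOP_CKI 4 and 1045 to 2405 in the other 3. That call was lost with GC centring, without any of the 5 control libraries or without SPOP_CKI 2, 3 or 4, and the log2 fold change was 1.92 without SPOP_CKI 4. Thbs1 and Thbs4 rose 9.20-fold and 10.4-fold. Col1a1, at 7830 ± 6723 against 2230 ± 718, and Col3a1, at 16120 ± 16508 against 3508 ± 849, did not pass (adjusted p = 0.17 and 0.0785), and both passed when library SPOP_CKI 3 was left out. They too were highest in SPOP_CKI 2 and SPOP_CKI 4, Col1a1 at 13923 and 16112 and Col3a1 at 24783 and 41279. The other SPOP_CKI libraries had 1059 to 4432 and 4206 to 5318, against 1394 to 3085 and 2543 to 4434 in controls. Matrix-remodelling genes had 2 of 19 higher and 2 lower (3 and 2 adjusted over the list alone, camera adjusted p = 0.132), with the collagen chaperone gene Serpinh1 2.38-fold higher and Timp4 8.08-fold lower. This list passed without SPOP_CKI 3, where 6 were higher, and 4 were higher without SPOP_CKI 5. Only 1 was higher without control library 1 or 4 or without SPOP_CKI 2 or 4.

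Of 20 transforming growth factor beta pathway genes, 8 rose and 0 fell (1 fell without SPOP_CKI 3; 9 and 1 adjusted over the list alone, median 0.36, camera adjusted p = 0.000901, and adjusted p = 0.519 with an estimated correlation). Inhba, a subunit of activin, rose 9.90-fold, Fstl1 rose 3.72-fold and Tgfb2 rose 3.46-fold. Of 10 activated fibroblast markers, 5 rose and 0 fell (7 and 0 adjusted over the list alone, median 2.52, camera adjusted p = 0.000632, and adjusted p = 0.527 with an estimated correlation). Several of these markers, Postn and Thbs4 included, are also in the extracellular matrix list. Without control library 1, 2, 3 or 4 or without SPOP_CKI 2 or 4, 3 were higher. Meox1 rose by 2.58 on the log2 scale, and Acta2, which smooth muscle also expresses, rose from 1511 ± 501 to 9252 ± 3843 (log2 fold change 2.58, SE 0.29, adjusted p = 0.000412). General fibroblast markers had 1 of 12 higher, Lum (2.31-fold), and 1 lower, Dpep1 (1 and 0 adjusted over the list alone, camera adjusted p = 0.171). The Dpep1 call was lost with GC centring, without control library 1, 3, 4 or 5 or without SPOP_CKI 1, 4 or 5, and 4 markers were higher without SPOP_CKI 3 and 2 without SPOP_CKI 1 or 5.

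Of 24 unfolded protein response genes, 13 rose and 1 fell (14 and 1 adjusted over the list alone), with a median of 0.77 on the log2 scale (camera, adjusted p = 3.86e-05, and adjusted p = 0.519 with an estimated correlation). Hspa5 (ENSMUSG00000026864, chromosome 2, 34771970 to 34777547), the main chaperone of the endoplasmic reticulum, rose from 4809 ± 1019 to 15385 ± 3556 (log2 fold change 1.68, SE 0.21, adjusted p = 0.000646). Sdf2l1 rose 4.16-fold and the asparagine synthetase gene Asns 3.32-fold, and 2 genes fell without SPOP_CKI 3. Among 16 heat shock genes, 4 rose and 1 fell (5 and 1 adjusted over the list alone, camera adjusted p = 0.0398, and adjusted p = 0.621 with an estimated correlation). This list call was lost with fry (adjusted p = 0.0528), without control library 3 or without SPOP_CKI 1, 2 or 3, and without the 3 libraries with Xist reads. The 1 gene lower lost its call without any of the 5 control libraries or without SPOP_CKI 4 or 5. Hsp90aa1 rose 4.49-fold, Hsph1 2.54-fold and Hspa8 2.16-fold. In the oxidative stress list 2 of 24 genes rose and 6 fell (3 and 6 adjusted over the list alone, camera adjusted p = 0.616), with Srxn1 4.49-fold higher and Sod1 2.29-fold and Keap1 2.31-fold lower. Without SPOP_CKI 5, 4 of these genes were higher, and 1 was higher without control library 1, 2, 3 or 4. In the p53 and apoptosis list 5 of 21 rose and 4 fell (7 and 5 adjusted over the list alone, camera adjusted p = 0.223). Eda2r rose 6.23-fold, Phlda3 3.88-fold and Bcl2 3.33-fold.

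Transcripts of proteins reported as SPOP substrates showed few changes, with 2 of 28 higher and 2 lower (2 and 2 adjusted over the list alone, camera adjusted p = 0.799). Caprin1 was 1.58-fold higher, G3bp1 1.34-fold higher, Sqstm1 2.21-fold lower and Erg 1.59-fold lower. The G3bp1 call was lost without any of the 5 control libraries or without SPOP_CKI 1 or 2, and centring by transcript GC content ended the calls of G3bp1 and Caprin1. Without SPOP_CKI 5, 4 were lower. The list median was 0.08 and its mean −0.03 on the log2 scale, and the median ran from −0.099 to 0.14 with 1 library left out. Cullin-3 adaptors and SPOP complex genes had 2 of 20 higher, Spop among them, and 5 lower (3 and 6 adjusted over the list alone, camera adjusted p = 0.816). Klhl38, at 0 in SPOP_CKI 3, fell 12.7-fold (6.36-fold without SPOP_CKI 3 and 19.9-fold without SPOP_CKI 5), and Klhl21 fell 2.84-fold. In the atrophy and proteasome list 8 of 22 genes fell and 2 rose (9 and 2 adjusted over the list alone, camera adjusted p = 0.0821, fry adjusted p = 0.00228). In camera the list passed without control library 5. Without control library 1, 1 was higher. The ubiquitin ligase genes Fbxo31, Fbxo32 and Trim63, the last 2 of them muscle ligases, fell 8.65-fold, 3.48-fold and 3.12-fold. Of 22 autophagy and lysosome genes, 9 fell and 2 rose (10 and 2 adjusted over the list alone, camera adjusted p = 0.102, fry adjusted p = 0.00318). They included Pink1 (2.78-fold lower) and the autophagy kinase gene Ulk1 (2.65-fold lower), both of which lost their calls when libraries were centred by GC content.

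Inflammatory cytokine genes had 5 of 20 higher and 1 lower (5 and 1 adjusted over the list alone, median 0.87, camera adjusted p = 0.01, and adjusted p = 0.834 with an estimated correlation). By fry this list did not pass (adjusted p = 0.224). The median moved to 0.47 without SPOP_CKI 2, where the list call was lost, and to 0.52 without SPOP_CKI 4, and 9 were higher without SPOP_CKI 3. The number lower was 0 without control library 1, 3, 4 or 5 or without SPOP_CKI 1, 2 or 5. Besides Ccl7, the monocyte chemoattractant gene Ccl2 rose 9.65-fold and the adhesion molecule gene Vcam1 3.21-fold. None of 24 interferon response genes and none of 15 antigen presentation genes passed in limma (0 adjusted over the list alone in both, camera adjusted p = 0.0987 and 0.876). At an unadjusted p under 0.05 limma gave 2 and 0, while 8 interferon genes passed in DESeq2 and 2 in edgeR, and 1 antigen presentation gene in DESeq2 and 0 in edgeR. The interferon list passed on the DESeq2 and edgeR results, and without SPOP_CKI 1, where 6 genes were higher, or SPOP_CKI 3, where 1 was. The antigen presentation list had a median of −0.12 and a mean of 0.02 on the log2 scale. Ifi44 stood at 459 ± 300.3 against 155 ± 25.8 and H2-D1 at 5159 ± 3104 against 7562 ± 1219 (limma adjusted p = 0.107 and 0.149), and Ifi44 passed without SPOP_CKI 1 and H2-D1 without SPOP_CKI 2.

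Markers of several cell types shifted with genotype. Ventricular cardiomyocyte markers fell in 6 of 12 and rose in 0 (8 fell adjusted over the list alone, median −0.89, camera adjusted p = 0.00127, and adjusted p = 0.527 with an estimated correlation), with Ckm 4.04-fold and the myoglobin gene Mb 2.49-fold lower. Several of these markers, Myh6 and Tnni3 included, are also in the sarcomere list, so these lists are not separate results. Endothelial markers fell in 8 of 12 and rose in 0 (8 adjusted over the list alone, median −0.83, camera adjusted p = 0.00315, and adjusted p = 0.519 with an estimated correlation). Fabp4, which adipocytes also express, fell 5.01-fold, Cldn5 3.21-fold and Tie1 2.11-fold. Erythroid transcripts fell in 5 of 7 and rose in 0 (6 adjusted over the list alone, median −1.23, camera adjusted p = 0.00184, and adjusted p = 0.519 with an estimated correlation), Hbb-bs from 9358 ± 3869 to 2771 ± 1226. Macrophage and monocyte markers had 4 of 17 higher and 1 lower (6 and 1 adjusted over the list alone, camera adjusted p = 0.0871). The list passed without SPOP_CKI 1, 3 or 5, and the number higher was 1 without control library 1, 3, 4 or 5 or SPOP_CKI 2 or 4 and 2 without control library 2. The macrophage gene Adgre1 rose 2.95-fold, a call lost with GC centring, without any of the 5 control libraries or without SPOP_CKI 2, 3 or 4, and the scavenger receptor gene Cd163 fell 2.19-fold. All 3 measured neutrophil markers, S100a8, S100a9 and Csf3r, rose 3.74-fold, 3.27-fold and 2.85-fold (3 adjusted over the list alone, adjusted p between 0.0345 and 0.047). None of the 3 passed without control library 1, 3 or 4 or without SPOP_CKI 4. Csf3r also lost its call without control library 2 or 5 or SPOP_CKI 2, and S100a8 without SPOP_CKI 2 or 5. GC centring ended the calls of S100a8 and S100a9.

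The libraries were not alike within SPOP_CKI. In library SPOP_CKI 3, 13167 genes had at least 1 read, against 18531 to 20806 in the other 9. Relative to the other SPOP_CKI libraries, its median log2 deviation was 0.42 in the lowest decile of transcript GC content and −1.66 in the highest. Of 9908 genes with a median of at least 100 in the other 9 libraries, 248 were at 0 in this library. Libraries SPOP_CKI 1, SPOP_CKI 3 and control 5, labelled male, had Xist at 4491 to 6578 scaled reads and 0 reads on 4 Y-linked genes (Ddx3y, Uty, Kdm5d and Eif2s3y). The other 7 libraries had 2589 to 3960 reads on those genes and Xist at most at 5.31. Without the 3 libraries, 1937 genes were higher and 2414 lower in SPOP_CKI, a comparison chosen after the data were seen.

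**Figure D3:**
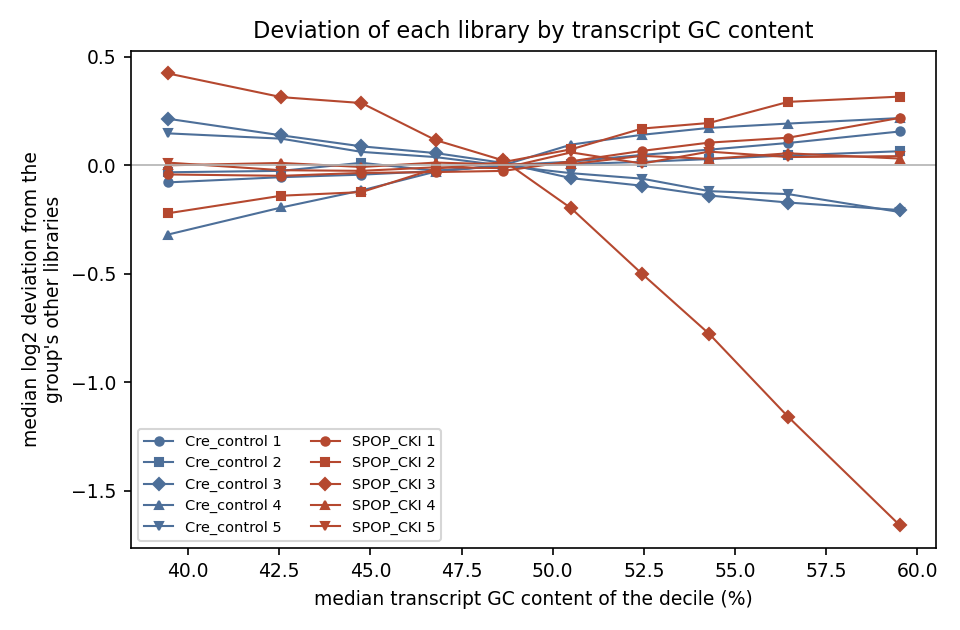
Median log2 deviation of each library from the other libraries of its group (vertical axis) in 10 classes of tested genes ordered by transcript GC content (horizontal axis, median percent of the class). Each line is a library, and library SPOP_CKI 3 runs from 0.42 to −1.66 whereas no other library falls by more than 0.421 from the lowest to the highest class.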

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

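The tests in this part were chosen after the results were seen, except that of read depth for library SPOP_CKI 3.

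A library was singled out where its gap to the nearest other library of its group, divided by the range of the group, passed the critical value of 0.71 for 5 libraries. Chance singles out about 1 in 20 groups, and here 23 of 386 groups (5.96%) were. Of the 23, 6 fell on SPOP_CKI 3, where Cd4 (0.737), Ehhadh (0.829), Keap1 (0.795), Lck (0.76), Polrmt (0.719) and Sqstm1 (0.728) were lowest. Control library 5 was lowest in the Y-linked genes Ddx3y (0.928), Eif2s3y (0.947), Kdm5d (0.931) and Uty (0.858) and highest in Xist (0.781). It was also lowest in Sbk2 (0.726) and highest in Ucp3 (0.713). Control library 4 was lowest in Cul3 (0.733), Dnm1l (0.786), Lum (0.775) and Tfrc (0.81) and highest in Hbb-bt (0.737). Control library 1 was lowest in Adam19 (0.723) and highest in Krt18 (0.845), and control library 3 was lowest in Lck (0.743). SPOP_CKI 2 was highest in Srxn1 (0.727) and SPOP_CKI 5 lowest in Prnp (0.797).

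Library SPOP_CKI 3 detected 13167 genes, against at least 18531 in every other library. Read depth did not account for this, since the other libraries thinned to its depth still detected at least 18493 genes, and neither did sex, since the other 2 libraries with Xist reads detected 18998 and 19469. The change in its median deviation from the lowest to the highest GC decile was −2.082 on the log2 scale. Among the other libraries the largest fall was −0.421 and the largest rise 0.538, the rise in SPOP_CKI 2. A loss of GC-rich transcripts in library SPOP_CKI 3 is therefore a candidate explanation for that shift. The 248 well-expressed genes at 0 in this library had a median GC content of 56.8%, against 49.5% for all such genes. With at least 10 reads it had 12629 genes, against 13973 to 14845 in the other libraries. Its shortfall thus lay mainly in genes with few reads, and whether a loss of GC-rich transcripts accounts for those was not tested. Whether such a loss arose in the RNA, in library preparation or in the animal was not tested.

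Libraries SPOP_CKI 1, SPOP_CKI 3 and control 5, labelled male, had Xist, the transcript that silences an X chromosome in female cells, at 4490.7 or more and no reads on 4 Y-linked genes. Mixed RNA of male and female animals is argued against by 0 Y-linked reads in each, where the other 7 libraries had at least 2589. An animal of the other sex than the label says may be the source, as Xist was at most 5.31 elsewhere. Sex as the whole source of the genotype calls is argued against by 2850 genes that changed with Xist status as a covariate, and by 4351 without the 3 libraries. Library SPOP_CKI 3 is among the 3, and leaving it out alone gave 4381 genes. How far the count of 4351 reflects sex or that library cannot be told apart. Sex is unevenly spread, with 2 such libraries in SPOP_CKI and 1 in controls, and the exclusion of the 3 libraries compared 3 SPOP_CKI with 4 control libraries that all had Y-linked reads. Among the libraries with Xist reads, 2 against 1, genotype was not tested.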

How the results depend on the processing

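The exclusion of Xist libraries, Xist status as a covariate, GC centring, and edgeR and camera without SPOP_CKI 3 were chosen after the data were seen. Among the 185 named genes other than Spop and the 46 tested lists, no called gene or list changed direction in any alternative that tested it. Of the genes without a call, 10 changed sign, in 24 results. GC centring moved Spopl from 0.14 to −0.29, Cul3 from 0.14 to −0.29 and Ppargc1a from 0.20 to −0.18. Array weights gave −0.049 for Cul3, −0.12 for Ppargc1a and 0.11 for Cd4, against −0.87. Without the Xist libraries Ppargc1a was at −0.089, Cd4 at 0.29 and Ighm at 0.016, against −0.48. Cd4 was at 0.037 under quantile normalization and 0.099 in edgeR without SPOP_CKI 3, which gave 0.13 for Jchain, against −1.34. A pseudocount of 0.5 gave −0.088 for Scgb3a1, against 0.049. With 1 library left out, Acta1 ran from −0.023 to 0.58, Pln from −0.65 to 0.031, Ppargc1a from −0.017 to 0.51, Cd4 from −1.29 to 0.047, Lck from −0.73 to 0.83 and Scgb3a1 from −0.25 to 0.77. Of the lists without a call, 12 changed the direction of the test, in 49 results, at the medians that follow, and the median itself changed sign for 11 lists. Fry, which does not compare a list with other genes, pointed against camera for antigen presentation (−0.12), cullin-3 adaptors (−0.080), SPOP substrates (0.080), adrenergic (0.16), angiotensin (0.063), angiogenesis (−0.067) and immediate early (−0.10) genes. Camera on the DESeq2 and edgeR results turned for cullin-3 adaptors (−0.088 and −0.074) and adrenergic genes (0.19 and 0.20). With the minimum of 50 it turned for antigen presentation (−0.28), angiogenesis (−0.077) and immediate early (−0.22) genes, and with GC centring for glucose metabolism (−0.17). The adrenergic list also turned with quantile normalization (0.24), array weights (0.035), the Xist libraries left out (0.14), and edgeR (0.24) and camera (0.20) without SPOP_CKI 3. The angiogenesis list turned with a pseudocount of 0.5 (−0.067), the replicate block (−0.067), array weights (−0.053), protein-coding genes (−0.067), Xist libraries left out (−0.071), Xist status (−0.051) and camera without SPOP_CKI 3 (−0.088). B and plasma cell markers (0.016) turned without the Xist libraries and epicardial markers (−0.38) in edgeR without SPOP_CKI 3. With 1 library left out, medians of lists that turned ran from −0.44 to −0.063 for calcium handling, −0.27 to 0.022 for mitochondrial biogenesis, −0.58 to 0.24 for antigen presentation, 0.097 to 0.20 for adrenergic, −0.11 to 0.027 for angiogenesis, −0.47 to 0.19 for immediate early and −0.48 to −0.24 for B and plasma cell genes. Of 162 called genes among these 185, 112 kept their call in every alternative that tested them, apart from an adjusted p under 0.01. The naming rule favours called genes with large fold changes, so this share can overstate how stable calls are. Of all 3168 calls, 1931 held without control library 1. Leaving out 1 library gave 1935 (control 1) to 4381 (SPOP_CKI 3) changed genes, 891 to 1930 higher and 1034 to 2451 lower, 433 to 794 higher and 661 to 1171 lower by over 1 on the log2 scale, and 5 to 9 lists higher and 8 to 9 lower. Array weights, which ran from 0.086 for SPOP_CKI 3 to 3.58 for control 1, called 5320 genes, 2429 higher, 2891 lower and 938 higher by over 1. An adjusted p under 0.01, stricter by construction, gave 1156, with 516 higher, 640 lower, 357 higher and 511 lower by over 1. For genes higher by over 1, against 607, DESeq2 gave 934, the authors' deposited test 1081, the libraries without Xist reads 1033 and edgeR without SPOP_CKI 3 1086. The last also called 2342 genes higher in all. The causes were not tested. On recovered reads edgeR called 3173 genes and DESeq2 4141. GC centring called 2537, with 1862 of the 3168 called the same way, and 21 of the 3168 had the opposite sign. Of the 162 called named genes, 30 lost their call under it. Lists higher numbered 7 and lists lower 8, against 11 and 11 with no filter and 4 and 12 with fry. With the minimum of 50, 1 called list lost its call, and with array weights 1 did. With an estimated correlation 0 were higher and 0 lower, also without SPOP_CKI 3, and the 15 called lists had adjusted p between 0.519 and 0.834. The replicate block called 2946 genes. Same-numbered libraries had correlations of deviations of 0.111, 0.104, 0.159, 0.0815 and 0.0265, only numbers 1 and 3 correlated best with their own number, and the numbers were not treated as pairs. In data simulated at this depth, with the same spread per gene in both groups, 20.4% of genes changed by 1 on the log2 scale were recovered. The real spread could be unequal, as the mean of the fatty acid oxidation list had an SD of 0.453 in SPOP_CKI and 0.054 in controls. Far fewer genes were changed in the simulation than the 3168 called here, which made the adjusted threshold stricter. That share can understate recovery in the real data, where a missing call still does not show that a gene is unchanged.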

Other observations

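The gene lists in this first part were fixed before the data were examined, and the tests of hypotheses further down were chosen after the results were seen.

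Of 14 targets of the glucocorticoid receptor, 8 were lower and 0 higher (9 lower and 1 higher adjusted over the list alone, median −1.23, camera adjusted p = 0.00184, and adjusted p = 0.519 with an estimated correlation). Without control library 4 or SPOP_CKI 1, 1 was higher. Hif3a fell from 134 ± 44.5 to 14.6 ± 19.4 (log2 fold change −4.00, −3.25 without SPOP_CKI 3, where it was at 0, and −4.65 without SPOP_CKI 5), Zbtb16 fell 6.60-fold and Per1 3.52-fold, and Pdk4, which is in this list too, fell 19.5-fold. Per1 is also a core clock gene, and of 18 circadian genes 7 fell and 1 rose (7 and 2 adjusted over the list alone, camera adjusted p = 0.142, fry adjusted p = 0.0276). The number higher was 0 without control library 1, 2 or 4 and 2 without control library 5 or SPOP_CKI 3. Cry2 fell 3.27-fold, a call lost without control library 1 or SPOP_CKI 4, and centring by GC content ended the call of Dbp (4.44-fold lower). Collection times of the hearts are not given in the sources used here. Among immediate early genes 3 of 22 rose and 4 fell (3 and 5 adjusted over the list alone, camera adjusted p = 0.923). Egr3 rose 11.8-fold and Egr2 7.62-fold. The number lower was 2 without control library 1 or 2 and 1 without control library 4, and 5 were higher without SPOP_CKI 3.

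In the adrenergic list 4 of 18 genes fell and 2 rose (4 and 2 adjusted over the list alone, camera adjusted p = 0.914). Beside Adra1a (log2 fold change −4.08, −3.05 without SPOP_CKI 3, where it was at 0), Adra1b fell 3.57-fold, while the phosphodiesterase gene Pde4b rose 2.42-fold, and 2 were lower without control library 1 or SPOP_CKI 4. In the angiotensin, endothelin and calcineurin list 3 of 23 rose and 3 fell (3 and 3 adjusted over the list alone, camera adjusted p = 0.721). The angiotensin receptor gene Agtr1a fell 2.49-fold and Edn3 rose 4.98-fold. The number higher was 1 without any control library or without SPOP_CKI 4. The oxygen sensor gene Egln3 rose 3.03-fold in the angiogenesis and hypoxia list, where 2 of 20 rose and 3 fell (2 and 4 adjusted over the list alone, camera adjusted p = 0.992). There 1 rose without control library 1, 2 or 4 or SPOP_CKI 4. Of 22 cell cycle genes, the cyclin genes Ccnd2 and Ccnd1 rose 2.61-fold and 2.20-fold and Cenpa fell 3.15-fold (2 and 1 adjusted over the list alone, camera adjusted p = 0.616), and 2 fell without SPOP_CKI 3 or 4. Of 26 ribosome and translation genes 1 rose and 2 fell (1 and 0 adjusted over the list alone, camera adjusted p = 0.339), and 4 fell without SPOP_CKI 3, 1 without control library 3 or 5 and 0 without control library 1, 2 or 4 or SPOP_CKI 4. Medians and means had opposite signs in the adrenergic list (0.16 and −0.44) and the angiotensin list (0.06 and −0.03). With 1 library left out, the angiotensin median ran from −0.022 to 0.15. Camera pointed upward against negative medians in the cell cycle (−0.02), angiogenesis (−0.07) and immediate early (−0.10) lists.

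Among other cell type markers, 2 of 12 smooth muscle and pericyte markers fell, with the pericyte channel gene Kcnj8 2.07-fold lower, and 1 rose, or 2 without SPOP_CKI 3 (1 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.432). Of 11 endocardial and lymphatic markers 2 rose, among them Nrg1 (3.06-fold), and 1 fell (2 and 1 adjusted over the list alone, camera adjusted p = 0.217). Only 1 rose without any control library or without SPOP_CKI 2 or 4. Of 7 atrial markers 2 rose, Nppa and Pam (1.71-fold), and 1 fell (3 and 2 adjusted over the list alone, camera adjusted p = 0.721), with a median of −0.65 and a mean of 0.21. The number lower was 0 without any control library or SPOP_CKI 2 or 4 and 2 without SPOP_CKI 5. Plin4 and Fabp4 fell among 4 adipocyte markers, Plin4 3.15-fold (3 lower adjusted over the list alone). Of 8 Schwann and neural markers 1 rose, Prnp (1.85-fold), of 10 epicardial markers 1 rose, Krt18, and of 5 skeletal muscle markers 1 fell, Ckm (1, 0 and 1 adjusted over the list alone, camera adjusted p = 0.432, 0.721 and 0.721). The Krt18 call was lost without any control library or without SPOP_CKI 1, 2 or 4, 1 epicardial marker fell without SPOP_CKI 1, 2 or 3, and 2 skeletal muscle markers fell without SPOP_CKI 3. No T or NK cell marker of 3 and no B or plasma cell marker of 7 passed in limma, DESeq2 or edgeR, and none had an unadjusted p under 0.05 in any of them.

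Genes in this paragraph were chosen after their values were seen. The iron exporter gene Slc40a1 fell by 1.25 on the log2 scale (limma, adjusted p = 0.00257) and the iron importer gene Slc11a2 rose by 0.59 (adjusted p = 0.0206), beside the 16.3-fold rise of Tfrc. Of other genes known to respond to the aryl hydrocarbon receptor, Tiparp rose by 0.91 (adjusted p = 0.00935), whereas Cyp1b1, Ahrr and Nqo1 did not pass (adjusted p = 0.327, 0.793 and 0.183). Library SPOP_CKI 2 had Iigp1 at 19273, against 399 to 1824 in the other 9 libraries. Timp1 stood at 7387 in SPOP_CKI 2 and 1817 in SPOP_CKI 4, and between 40.3 and 152 in the other SPOP_CKI libraries.

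Splits of the 10 libraries were compared with the real one. Of 100 splits out of 126, the real one included, 1 gave as many as 3168 changed genes, the highest other giving 1, so chance is argued against for that count. As many as 15 lists were called in 40 of the 100 splits, with 26 at most in another. All of these 40 splits kept libraries SPOP_CKI 2 and SPOP_CKI 4 on the same side, and splits that parted them gave at most 11 lists. The number of lists thus followed differences between hearts, so these splits are no measure of chance for it. Chance is neither excluded nor made likelier by them.

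The fall of fatty acid oxidation genes was weighed against 3 explanations. A lower share of cardiomyocytes as the whole source is argued against, as far as ventricular cardiomyocyte markers track that share. The mean change of the list minus that of these markers was −0.641 on the log2 scale (exact permutation p = 0.0079, the smallest the arrangements allow). The median change was −1.34 for the list and −0.89 for the markers, a smaller gap. Some of the markers, such as Myh6 and Tnni3, are sarcomere genes whose level within cardiomyocytes may itself change. Endothelial and fibroblast markers moved apart by −1.26 (exact permutation p = 0.0079), which does not bear on the share of cardiomyocytes. Relative to the cardiomyocyte markers, endothelial markers changed by 0.12 (exact permutation p = 0.587). A loss of GC-rich transcripts in SPOP_CKI 3 is argued against by 25 members that were lower without it. A lower output of genes driven by PPAR receptors stays open. The 7 measured PPAR targets outside the fixed lists, all lower, had a median of −1.23, against −0.71 for oxidative phosphorylation and −0.92 for tricarboxylic acid cycle genes, and their mean changed by −1.166 relative to those genes (−0.88 without SPOP_CKI 3, where Ehhadh was at 0). These targets were chosen after the data were seen, so the comparison decides nothing, and receptor activity was not measured, with Pparg lower by −1.19 (adjusted p = 0.000525) and Ppara not passing (adjusted p = 0.799).

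Within the unfolded protein response, endoplasmic reticulum chaperone genes rose more than targets of the transcription factor ATF4, by 1.019 on the log2 scale on average (0.77 without SPOP_CKI 3). Of 16 chaperone genes 13 were higher and 1 lower, and of 15 ATF4 targets 2 were higher and 2 lower. Both of these lists were chosen after the data were seen, so the difference decides nothing about the arms of the response.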
